A study of Escherichia coli with 15 samples.

How the data were processed

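RNA of Escherichia coli K-12 MG1655 was measured on 15 Affymetrix E. coli Antisense Genome arrays, which carry probe sets for the genes of this strain, for intergenic regions and for controls. The labels give 5 groups of 3 arrays: biofilm on glass in flow cells at 2 h (attachment), 24 h (colony formation) and 72 h (maturation), and planktonic culture in exponential phase (6 h) or in stationary phase (sampled at 24 h), all in MOPS minimal medium with 0.2% glucose at 37 °C. Per the labels' protocols, RNA was stabilised before extraction, depleted of ribosomal RNA, polyadenylated, and amplified from oligo(dT) primers into biotin-labelled cRNA. The design text says that the experiments were repeated 3 times. No label says how separate the 3 cultures of a group were, so the p-values measure the spread between these samples, which may in part be technical.

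The deposited values are array intensities on a linear scale, 1 per probe set and array, between 0 and 15494. The software, the summary of probes into probe sets and the scaling by which the authors made them are not given in the sources used here. The median signal of an array lay between 68.7 and 127, and the tables held 101 zeros, 0 to 14 per array. With 3 arrays per group the number of arrays limits the precision.

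Of the 7312 probe sets, 4345 were gene probe sets by their identifier. A platform annotation table tied 4231 of them to 1 gene of K-12 (4188 genes, 41 of them with several probe sets), 41 to several genes and 72 to none, and in 1 case it disagreed with the identifier. Only the 4231 entered the tests, and counts of results in a comparison are counts of these probe sets, while each gene counts once in a list. Another 2886 probe sets were intergenic, 22 were controls and 59 belonged to phages, plasmids or vectors. Of the 4231, 83 carry a suffix that marks probes shared between genes. The genome build behind the probe positions is not given in the sources used here, so genes are named by symbol and b number without coordinates.

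Values under 5.3, the 5th percentile of the table, were raised to it, and log2 was taken. The array medians of the gene probe sets then spanned 1.21 on the log2 scale, above the limit of 0.5 set before the data were examined, so the arrays were quantile normalized. Group means were fitted over all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-variance trend, 10 residual degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the 4231 probe sets, and a probe set passed at an adjusted p under 0.05. Every adjusted p of a gene is from limma. Errors of log2 differences are standard errors of this fit with 3 arrays per group. The 12 comparisons were the 10 pairs of groups, the mean of the 3 biofilm stages against the mean of the 2 planktonic phases, and the change from attachment to colony formation against the change from exponential to stationary phase. The 44 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons. No list passed when the correlation between its genes was estimated instead, and that second adjusted p is given beside the lists named or as a range over them.

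An array's background was the 95th percentile of its 59 phage, plasmid and vector probe sets. A gene above it on none of a group's arrays has only a bound there. The bound is the mean of the brighter group minus the mean, over the arrays of the dimmer group, of the higher of the lowest normalized value above background and the probe set's own value, and it is written as "at least N-fold" with the adjusted p of the fit. No fold is given where both groups lay below background or the bound was under 1. Where a gene was above background on only some arrays of a group, their number is given.

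The genes named were set by a rule fixed before the data were examined. For 6 of the comparisons it took the 10 largest gains and the 10 largest losses of at least 2-fold with groups that did not overlap, a mean in the higher group above the median of all genes, no suffix for shared probes and at most 2 genes of one 3-letter stem. For each list it took up to 4 of its members with the largest changes that passed. The text names a part of these. Where a gene was chosen after its values were seen, that is said.

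Replicate numbers come from the sample titles. Deviations from the group means were correlated across genes between same-numbered arrays of different biofilm stages. All 9 pairs (r = 0.111 to 0.300) were above the limit of 0.1, so the numbers were taken to pair the biofilm arrays. Of the other 21 same-numbered pairs, 2 were above 0.1. Of 60 differently numbered pairs, 5 were above 0.1, such as attachment replicate 1 with maturation replicate 2 (0.197). Between biofilm stages, replicate 3 correlated negatively with replicates 1 and 2 (-0.302 to -0.115). Deviations from a mean cancel within a group, so positive same-numbered pairs force part of this. Replicate 1 of a stage with replicate 2 of another gave -0.0101 to 0.197. Replicates 1 and 2 thus tended to go together against replicate 3. They may be less separate than 3 arrays per group imply, and the p-values would then be too small. A replicate block, used as an alternative, tied same-numbered arrays of all 5 groups, although most pairs with planktonic arrays lay under the limit. The fit without the block was the one fixed beforehand and is reported.

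The fit was tested on simulated arrays, made 5 times from each gene's mean and its spread within groups, with 200 of 4231 probe sets changed between attachment and exponential phase. It recovered 31.6% of those changed 1.5-fold, 70.8% at 2-fold and 97.0% at 4-fold, and 3.63% of the calls were false. A list shifted by 0.7 was found in 5 of 5 simulations and 0 of 215 tests of unchanged lists passed. The simulated arrays were drawn gene by gene, without correlation between genes. In the data, the estimated correlation within a list lay between -0.0808 (autotransporter adhesins) and 0.792 (tricarboxylic acid cycle). The simulations therefore cannot tell how often unchanged lists of correlated genes would pass at the preset correlation.

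The alternatives were an offset in place of the floor, no floor, the values as deposited, median centring, a filter on dim probe sets, no variance trend, array weights, only the groups compared, intergenic probe sets in the fit, the replicate block and each array left out. A further 3 (the stationary arrays left out, only genes above background on at least 3 arrays, and replicates 1 and 2 of each biofilm stage averaged) were added after the data had been seen. With the values as deposited, the median of all genes shifted between the groups, by amounts given with the comparisons, and the normalized changes leave such shifts out.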

Results

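Transcript levels were compared between 3 stages of biofilm growth on glass and 2 phases of planktonic growth of E. coli MG1655, with 3 arrays per group. The 9 biofilm and 3 exponential arrays had 56.2% to 67.2% of gene probe sets above background, and the 3 stationary arrays 20.8% to 22.1%. The first principal component held 67.7% of the variance and set the stationary arrays apart, and the second held 19.2% and ordered the biofilm stages. Replicate 3 of colony formation lay at 18.2 on the second component, toward maturation (49.3 to 51.5), while replicates 1 and 2 lay at 2.75 and 1.69. Control probe sets had a median log2 signal of 4.99 ± 0.178 (SD, n = 3) on the stationary arrays, against 3.62 ± 0.102 at attachment and 4.04 ± 0.105 at maturation.

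**Figure D1:**
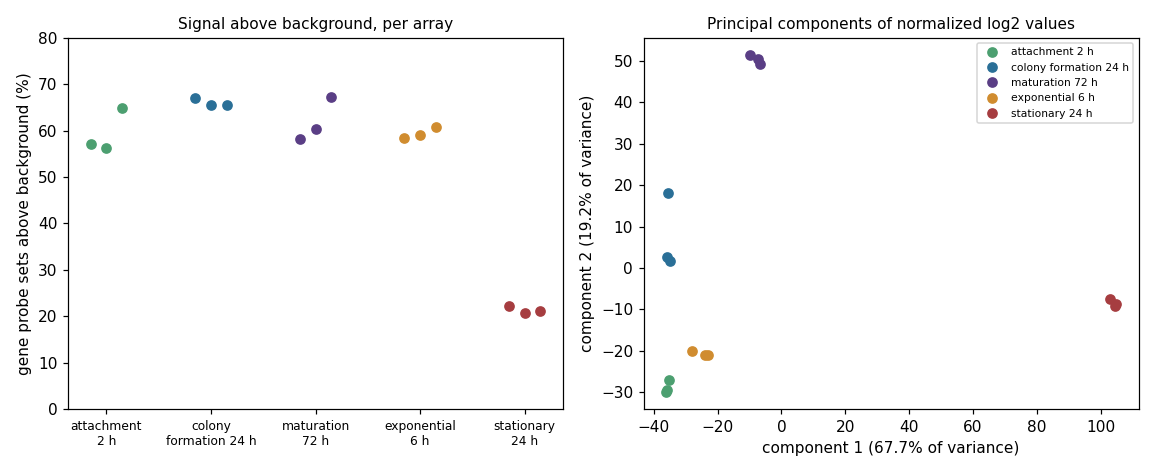
Left, the percentage of 4231 gene probe sets above background on each array (points), by group. Right, the arrays on the first 2 principal components of the normalized log2 values; the stationary arrays lie at 103 to 105 on component 1, and 1 colony formation array lies at 18.2 on component 2.

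The first comparison asked how newly attached cells differed from exponential planktonic cells. They were sampled at 2 h and 6 h, so growth mode and sampling time cannot be told apart in it. Genes of nitrogen limitation, iron acquisition and cold shock were higher in attached cells, and genes of copper and zinc homeostasis, acid resistance, heat shock and the RpoS general stress regulon were lower. The nitrogen signalling protein gene glnK (b0450) was at least 7.58-fold higher (adjusted p = 9.76e-06). Its neighbour amtB, the ammonium channel, was 7.87-fold higher (2.98 ± 0.29 on the log2 scale, adjusted p = 9.76e-06). The regulator gene nac was at least 5.80-fold higher (adjusted p = 1.08e-07). cspA (b3556), the major cold shock protein gene, was 9.82-fold higher (3.30 ± 0.13 on the log2 scale, adjusted p = 5.52e-10). The opposite held for ykgM (b0296), a spare ribosomal protein gene repressed by zinc, which was at least 46.1-fold lower (adjusted p = 3.72e-10). zinT (b1973), a periplasmic zinc binding protein gene, was at least 33.0-fold lower (adjusted p = 1.74e-05). znuA, the binding protein of the zinc transporter, was 14.8-fold lower, and pliG, a lysozyme inhibitor gene, was at least 11.95-fold lower.

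Of 40 nitrogen limitation genes, 13 rose and 1 fell (17 and 1 adjusted over the list alone; list adjusted p = 4.12e-06, and adjusted p = 0.327 with an estimated correlation). Of 37 iron acquisition genes, 23 rose and 1 fell (24 and 1 adjusted over the list alone; list adjusted p = 1.01e-09, and adjusted p = 0.122 with an estimated correlation). Among them, the siderophore receptor gene fiu was at least 2.75-fold and the enterobactin synthesis gene entE at least 2.61-fold higher, and the receptor gene fepA was 2.92-fold higher, with 2 of 3 exponential arrays above background. Of 13 iron-sulfur cluster assembly genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone; list adjusted p = 3.55e-05, and adjusted p = 0.0658 with an estimated correlation). Among 24 purine and pyrimidine synthesis genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone; list adjusted p = 2.65e-06, and adjusted p = 0.0875 with an estimated correlation), pyrD by 2.33-fold. The cold shock list had 4 of 12 members higher and 0 lower (5 and 0 adjusted over the list alone; list adjusted p = 1.63e-05, and adjusted p = 0.0658 with an estimated correlation). Besides cspA these were cspG (at least 2.35-fold), cspB (at least 4.29-fold) and the RNA helicase gene deaD (3.05-fold).

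Of 50 RpoS genes, 0 rose and 27 fell (0 and 29 adjusted over the list alone; list adjusted p = 1.85e-10, and adjusted p = 0.236 with an estimated correlation), such as osmB (3.19-fold) and msyB (2.95-fold). Of 19 acid resistance genes, 0 rose and 11 fell (2 and 11 adjusted over the list alone; list adjusted p = 5.97e-05, and adjusted p = 0.332 with an estimated correlation). The regulator gene gadE was 9.62-fold and the glutamate decarboxylase gene gadA 8.16-fold lower, each above background on 1 of 3 attachment arrays, and gadB was 4.68-fold lower. Without attachment replicate 3, the fitted gadE difference was 14.5-fold. No attachment array was then above background, so this is not a measured size. Of 20 heat shock genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone; list adjusted p = 3.49e-07, and adjusted p = 0.236 with an estimated correlation), with the chaperone genes clpB 4.04-fold and dnaK 3.09-fold lower. The ribosome hibernation genes rmf (3.59-fold lower) and hpf and the nucleoid gene dps (2.31-fold lower, lost without attachment replicate 1 or replicate 2) were among 4 of 6 members of their list that fell, with 0 that rose (4 and 0 adjusted over the list alone; list adjusted p = 0.000249, and adjusted p = 0.0658 with an estimated correlation). Copper and zinc homeostasis had 9 of 19 members lower and 1 higher (9 and 1 adjusted over the list alone; list adjusted p = 1.54e-06, and adjusted p = 0.0869 with an estimated correlation), including copA (6.09-fold) and cueO (5.47-fold), which export and oxidise copper. In all, 781 of 4231 gene probe sets differed, 396 higher and 385 lower in attachment, and 132 and 149 of these by at least 2-fold. The share of higher probe sets was 50.7%, and 31.1% with the values as deposited, in which the median of all genes shifted by -0.12. Without attachment replicate 2, 504 probe sets passed, and 1749 passed with array weights. Averaging replicates 1 and 2 of each biofilm stage left 437.

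The second comparison followed the biofilm from attachment to colony formation. Genes of low-oxygen and anaerobic metabolism and of acid resistance rose, and genes of iron acquisition, the tricarboxylic acid cycle and nitrogen limitation fell. The hydrogenase 1 genes hyaE and hyaF were at least 4.22-fold and 5.19-fold higher (adjusted p = 1.26e-06 and 6.03e-07). Without replicate 3 of colony formation these bounds were 2.47-fold and 3.25-fold. narH, a nitrate reductase subunit gene, was at least 6.69-fold higher (adjusted p = 5.57e-06). So were appB, a cytochrome bd oxidase subunit gene, at least 6.90-fold (adjusted p = 1.67e-07), and dmsB, a dimethyl sulfoxide reductase subunit gene, at least 7.37-fold (adjusted p = 4.24e-08). ydfZ (b1541) was 23.1-fold higher (4.53 ± 0.27 on the log2 scale, adjusted p = 3.29e-08). The copper efflux gene cusC was at least 5.16-fold higher.

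Of 69 low-oxygen genes, 51 rose and 0 fell (53 and 1 adjusted over the list alone; list adjusted p = 1.49e-28, and adjusted p = 0.0658 with an estimated correlation). Of 19 acid resistance genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone; list adjusted p = 8.50e-11, and adjusted p = 0.138 with an estimated correlation). gadB was 18.4-fold higher (4.20 ± 0.27 on the log2 scale, adjusted p = 4.86e-08) and gadA 21.8-fold, with gadA above background on 1 of 3 attachment arrays. Iron acquisition had 27 of 37 members lower and 2 higher (29 and 2 adjusted over the list alone; list adjusted p = 9.42e-15, and adjusted p = 0.0792 with an estimated correlation), with fiu at least 3.85-fold and fhuF 4.95-fold lower. Of 13 iron-sulfur cluster assembly genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone; list adjusted p = 7.72e-08, and adjusted p = 0.0565 with an estimated correlation), with hscB 2.04-fold and sufA 2.07-fold lower. Of 15 tricarboxylic acid cycle genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone; list adjusted p = 6.33e-10, and adjusted p = 0.272 with an estimated correlation), with the succinate dehydrogenase genes sdhA 4.84-fold and sdhC 4.18-fold lower (sdhA 3.10-fold without replicate 3 of colony formation). Of 40 nitrogen limitation genes, 20 fell and 0 rose (22 and 0 adjusted over the list alone; list adjusted p = 1.67e-08, and adjusted p = 0.237 with an estimated correlation), with glnK 5.72-fold, amtB 4.33-fold and nac 4.02-fold lower. The oxidative stress list had 13 of 25 members lower and 2 higher (14 and 2 adjusted over the list alone; list adjusted p = 0.000188, and adjusted p = 0.0864 with an estimated correlation), among them the superoxide dismutase gene sodA (5.34-fold lower, and 3.20-fold without replicate 3 of colony formation) and the glutaredoxin gene grxA (5.02-fold lower). The biofilm regulator gene bssR, chosen after its values were seen, was at least 11.4-fold higher (adjusted p = 4.86e-08).

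In this step 983 probe sets differed, 473 higher and 510 lower, and 216 and 200 of these by at least 2-fold. Of these, 48.1% were higher, and 79.6% with the values as deposited (median shift 0.24). Replicate 3 of colony formation had a normalized log2 signal of 10.48 for hyaF, against 8.57 and 8.33 in replicates 1 and 2, and 863 probe sets passed without it. With array weights 2213 probe sets passed, and 505 with replicates 1 and 2 of each stage averaged.

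**Figure D2:**
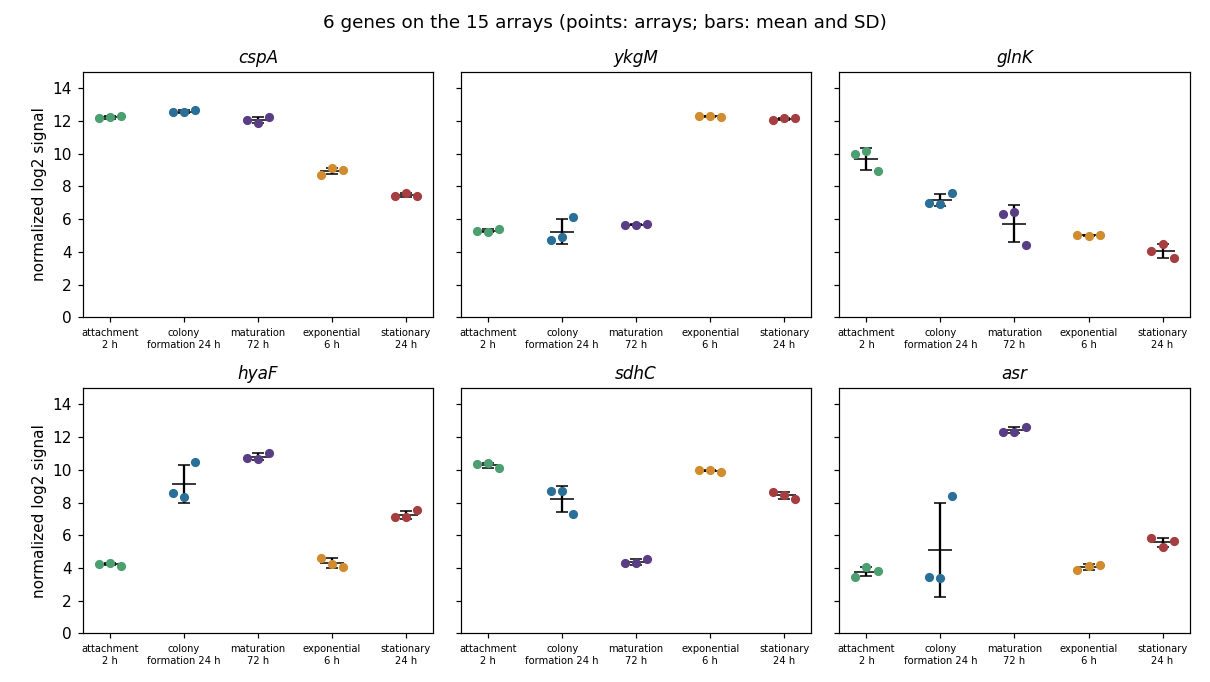
Normalized log2 signal of cspA, ykgM, glnK, hyaF, sdhC and asr on each of the 15 arrays (points) by group, with the group mean and SD (bars, n = 3). cspA was 12.1 to 12.6 on average in the biofilm stages and 8.93 in exponential cells, and asr reached 12.4 at maturation.

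The third comparison followed the biofilm from colony formation to maturation. Genes of heat shock, toxin-antitoxin pairs, iron-sulfur cluster assembly and low-oxygen metabolism rose, and genes of aerobic respiration, the tricarboxylic acid cycle and purine, pyrimidine and amino acid synthesis fell. grxA was 65.5-fold higher (6.03 ± 0.24 on the log2 scale, adjusted p = 2.95e-10), the biofilm regulator gene bssS (b1060) was 19.3-fold higher (4.27 ± 0.18, adjusted p = 6.23e-10). The hydrogenase maturation gene hypA was 16.6-fold higher (4.05 ± 0.21, adjusted p = 3.83e-09). The acid shock gene asr (b1597) was higher by 7.33 ± 0.90 on the log2 scale (adjusted p = 1.58e-05) and the alanine exporter gene alaE by 5.56 ± 0.80 (adjusted p = 6.57e-05). Each was above background on 1 of 3 colony formation arrays, with an SD of 2.89 for asr and 2.53 for alaE there, so the size of both changes is uncertain. asr was at 8.42 in replicate 3 of colony formation and at 3.47 and 3.38 in replicates 1 and 2. Without replicate 3, no colony formation array lay above background for either gene. The differences fitted there, 9.003 for asr and 7.01 for alaE, rest on signal below background and are not measured sizes. cyoA, a subunit gene of cytochrome bo oxidase, was at least 6.72-fold lower (adjusted p = 3.87e-07), and sdhC at least 3.16-fold lower (adjusted p = 1.24e-07). livJ, the binding protein gene of branched-chain amino acid uptake, was 10.6-fold lower (adjusted p = 1.49e-07).

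Of 20 heat shock genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone; list adjusted p = 6.54e-09, and adjusted p = 0.185 with an estimated correlation). The small chaperone gene ibpA was 17.5-fold higher and ibpB 92.4-fold, with ibpB above background on 1 of 3 colony formation arrays, and rpoH, the heat shock sigma factor gene, was 5.52-fold higher. Of 26 toxin-antitoxin genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone; list adjusted p = 3.39e-10, and adjusted p = 0.0869 with an estimated correlation), with yhaV 6.52-fold and higB at least 3.77-fold higher. Of 22 SOS genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.00374, and adjusted p = 0.156 with an estimated correlation), the excision repair gene uvrB by 4.32-fold. Iron-sulfur cluster assembly, lower at colony formation than at attachment, now had 10 of 13 members higher and 0 lower (11 and 0 adjusted over the list alone; list adjusted p = 3.81e-05, and adjusted p = 0.0658 with an estimated correlation), with hscB 2.69-fold higher. Of 69 low-oxygen genes, 38 rose and 6 fell (39 and 6 adjusted over the list alone; list adjusted p = 1.54e-06, and adjusted p = 0.282 with an estimated correlation), with the lactate dehydrogenase gene ldhA 9.20-fold higher.

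All 28 aerobic respiration and ATP synthase genes fell (28 adjusted over the list alone; list adjusted p = 2.64e-09, and adjusted p = 0.327 with an estimated correlation), cyoB by 8.77-fold (14.5-fold without replicate 3 of colony formation), with 1 of 3 maturation arrays above background. Of 15 tricarboxylic acid cycle genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone; list adjusted p = 4.64e-07, and adjusted p = 0.346 with an estimated correlation), sdhD by at least 7.31-fold. Of 77 amino acid biosynthesis genes, 41 fell and 4 rose (44 and 4 adjusted over the list alone; list adjusted p = 1.09e-05, and adjusted p = 0.170 with an estimated correlation), with the leucine synthesis genes leuB 3.46-fold and leuC 3.26-fold lower. Of 24 purine and pyrimidine synthesis genes, 17 fell and 0 rose (17 and 0 adjusted over the list alone; list adjusted p = 3.28e-06, and adjusted p = 0.0905 with an estimated correlation), with purB 3.17-fold lower. In this step 1898 probe sets differed, 846 higher and 1052 lower, and 445 and 421 of these by at least 2-fold, with a shift of -0.14 in the median of all genes as deposited. Without replicate 3 of colony formation 1849 probe sets passed, and 2848 with array weights.

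Set against exponential cells, colony formation differed in 962 gene probe sets (457 higher, 505 lower) and maturation in 2019 (906 higher, 1113 lower). At both stages all 15 tricarboxylic acid cycle genes were lower (15 and 15 adjusted over the list alone; list adjusted p = 2.11e-13 and 8.92e-12, and adjusted p = 0.205 and 0.236 with an estimated correlation). At maturation sdhA was at least 19.7-fold and sdhC at least 10.4-fold lower. Of 69 low-oxygen genes, 50 were higher and 1 lower at colony formation and 56 were higher and 2 lower at maturation (54 and 59 higher, 1 and 3 lower, adjusted over the list alone; list adjusted p = 5.32e-27 and 2.09e-21, and adjusted p = 0.0658 and 0.0771 with an estimated correlation). At maturation the nitrite reductase gene nirD was at least 21.2-fold and asr at least 50.9-fold higher. Maturation and attachment differed in 2329 probe sets, 1049 higher and 1280 lower at maturation, and 19 of 20 heat shock genes were higher there (20 adjusted over the list alone; list adjusted p = 2.88e-09, and adjusted p = 0.173 with an estimated correlation). For colony formation against exponential cells 47.5% of the probe sets were higher, and 67.4% with the values as deposited (median shift 0.12). For maturation against attachment the shares were 45.0% and 58.3% (median shift 0.09). For maturation against exponential cells they were 44.9% and 50% (median shift -0.005). With array weights, 1964 probe sets differed between colony formation and exponential cells.

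**Figure D3:**
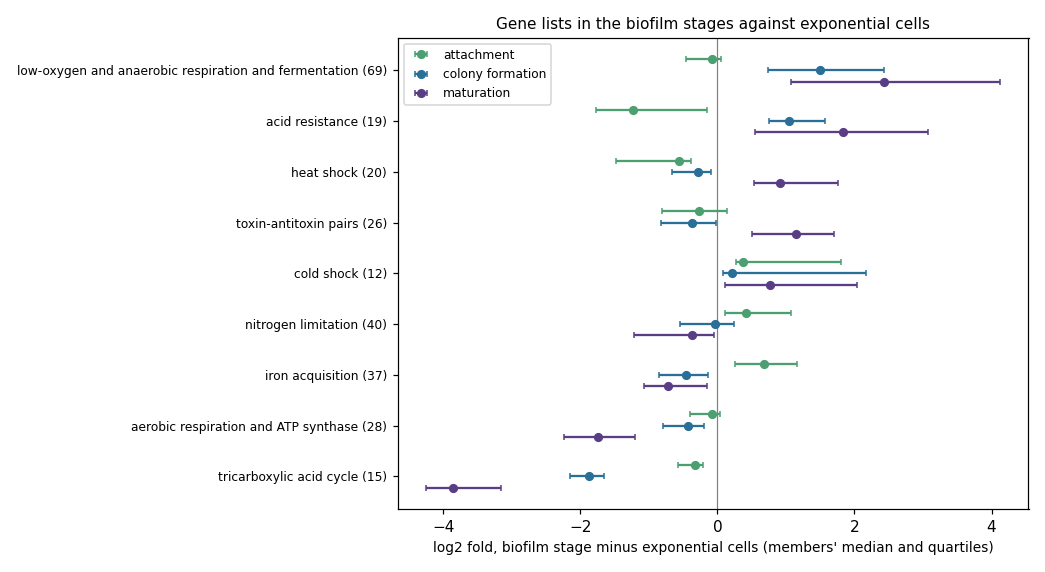
Median (points) and quartiles (bars) of the log2 difference from exponential cells over the measured members of 9 gene lists, for each biofilm stage. The median of the tricarboxylic acid cycle list moved from -0.33 at attachment to -1.88 at colony formation and -3.86 at maturation, and that of the low-oxygen list from -0.08 to 1.49 and 2.43.

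Exponential and stationary cells were compared to follow ageing outside the biofilm. In stationary cells, genes of ribosomal proteins, amino acid, purine and pyrimidine synthesis, and aerobic respiration were lower, and genes of the RpoS regulon, of fatty acid degradation and of toxin-antitoxin pairs were higher. bssR (b0836) was 60.0-fold higher (5.91 ± 0.25 on the log2 scale, adjusted p = 1.87e-11). yjfN was 55.6-fold higher (5.80 ± 0.25, adjusted p = 2.35e-11; 2 of 3 exponential arrays above background). nrdD, the anaerobic ribonucleotide reductase gene, was at least 44.2-fold higher (adjusted p = 3.97e-10). Lower in stationary cells were the ribosomal protein gene rplW (at least 7.24-fold, adjusted p = 1.87e-14), the methionine synthase gene metE (at least 11.8-fold, adjusted p = 1.47e-13) and the glutamate synthase gene gltB (at least 5.47-fold, adjusted p = 1.08e-12). Genes such as yfdE and ompL passed the test but lay below background in both phases, so no fold is given.

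Of 54 ribosomal protein genes, 53 fell and 1 rose (53 and 1 adjusted over the list alone; list adjusted p = 4.74e-16, and adjusted p = 0.0869 with an estimated correlation). Of 77 amino acid biosynthesis genes, 72 fell and 2 rose (72 and 2 adjusted over the list alone; list adjusted p = 2.11e-13, and adjusted p = 0.0658 with an estimated correlation). Of 24 purine and pyrimidine synthesis genes, 23 fell and 1 rose (23 and 1 adjusted over the list alone; list adjusted p = 6.49e-09, and adjusted p = 0.0721 with an estimated correlation). Of 23 aminoacyl-tRNA synthetase genes, 20 fell and 1 rose (20 and 1 adjusted over the list alone; list adjusted p = 1.09e-05, and adjusted p = 0.0658 with an estimated correlation). All 28 aerobic respiration genes fell (28 adjusted over the list alone; list adjusted p = 8.79e-10, and adjusted p = 0.317 with an estimated correlation). Of 50 RpoS genes, 40 rose and 4 fell (41 and 4 adjusted over the list alone; list adjusted p = 2.01e-06, and adjusted p = 0.346 with an estimated correlation), with yodD 27.1-fold and ymgE 17.5-fold higher. Of 9 fatty acid degradation genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.00324, and adjusted p = 0.133 with an estimated correlation), with the acyl-CoA synthetase gene fadD 27.9-fold higher and the acyl-CoA dehydrogenase gene fadE at least 37.6-fold higher. Of 26 toxin-antitoxin genes, 18 rose and 3 fell (18 and 3 adjusted over the list alone; list adjusted p = 0.00194, and adjusted p = 0.346 with an estimated correlation), with the toxin gene relE 20.4-fold higher. Of 69 low-oxygen genes, 45 rose and 7 fell (45 and 7 adjusted over the list alone; list adjusted p = 0.000112, and adjusted p = 0.372 with an estimated correlation), but only 18 of the 45 lay above background on a stationary array.

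Between the planktonic phases 3297 probe sets differed, 1695 higher and 1602 lower in stationary phase, and 1037 of the 3297 lay below background in both. The share of higher probe sets fell from 51.4% to 32.9% with the values as deposited (median shift -0.64).

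Colony formation and stationary phase were both sampled at 24 h. At this time genes of ribosomal proteins were higher in the biofilm, and genes of the RpoS regulon and fatty acid degradation were lower. ftnA, a ferritin gene, was at least 3.16-fold higher in the biofilm (adjusted p = 1.80e-11), and fimI, of the type 1 fimbriae, at least 2.88-fold higher (adjusted p = 3.21e-08), or 5.13-fold without replicate 3 of colony formation. ykgM was at least 57.9-fold lower (adjusted p = 4.95e-12), and fadE at least 52.7-fold lower (adjusted p = 8.72e-12). nrdI was at least 51.2-fold lower (adjusted p = 4.11e-10), and yjfN 72.9-fold lower (adjusted p = 1.07e-11). All 54 ribosomal protein genes were higher (54 adjusted over the list alone; list adjusted p = 2.24e-15, and adjusted p = 0.0869 with an estimated correlation). Of 50 RpoS genes, 41 were lower and 4 higher (41 and 4 adjusted over the list alone; list adjusted p = 5.20e-07, and adjusted p = 0.332 with an estimated correlation), with ymgE 37.9-fold lower. Of 9 fatty acid degradation genes, 8 were lower and 1 higher (8 and 1 adjusted over the list alone; list adjusted p = 0.00217, and adjusted p = 0.120 with an estimated correlation). Of the 4231 gene probe sets 3395 differed, 1677 higher and 1718 lower in the biofilm, with 890 below background in both groups. Attachment and maturation differed from stationary cells in 3360 (1641 higher) and 3331 (1632 higher) probe sets, and at both, 54 and 53 ribosomal protein genes were higher (54 and 53 adjusted over the list alone; list adjusted p = 1.13e-15 and 2.24e-15, and adjusted p = 0.0869 for each with an estimated correlation). With the values as deposited, the shares of probe sets higher in attachment, colony formation and maturation were 62.9%, 69.5% and 70%, against 48.8%, 49.4% and 49.0%, with shifts of 0.50, 0.86 and 0.75 in the median of all genes.

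The last comparison asked which genes set every biofilm stage apart from both planktonic phases. Of the genes in this paragraph, asnA and mepM were picked after their values were seen. Some cold shock genes were higher at every stage, while most members of their list moved less. Of its 12 genes, 5 were higher and 0 lower at colony formation than in exponential cells (5 and 0 adjusted over the list alone; list adjusted p = 0.000279, and adjusted p = 0.0828 with an estimated correlation). At maturation 8 were higher and 1 lower (8 and 2 adjusted over the list alone; list adjusted p = 0.00791, and adjusted p = 0.156 with an estimated correlation). cspA was 9.82-fold, 12.5-fold and 8.81-fold above exponential cells at attachment, colony formation and maturation. It was at least 8.004-fold, 10.2-fold and 7.18-fold above stationary cells. deaD was 3.05-fold, 3.23-fold and 3.35-fold above exponential cells and at least 3.45-fold, 3.65-fold and 3.79-fold above stationary cells. lpxP, a lipid A acyltransferase gene known from growth in the cold, was at least 1.46-fold, 2.84-fold and 2.33-fold above exponential cells. asnA, the ammonia-dependent asparagine synthetase gene, was 5.01-fold, 4.27-fold and 9.31-fold above them. ykgM was at least 46.1-fold, 64.5-fold and 52.3-fold below exponential cells and at least 41.4-fold, 57.9-fold and 47.0-fold below stationary cells. mepM (b1856), a murein endopeptidase gene beside znuA, was 3.86-fold, 2.92-fold and 3.20-fold below exponential cells, and the periplasmic stress gene osmY 2.24-fold, 3.84-fold and 9.05-fold. The osmY difference at attachment was lost when any of 5 arrays was left out.

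In all 6 comparisons 85 probe sets of 84 genes differed in the same direction, 36 probe sets (35 genes) higher and 49 lower in the biofilm, and 10 and 13 probe sets by at least 2-fold each time. Groups with no effect, simulated 20 times against the shared arrays, gave 0, and independent lists of these sizes would share 0.543 higher and 0.801 lower probe sets. The simulated value leaves out all real effects and the other one leaves out the shared arrays, so neither is the count to be met without a shared effect, and part of the excess over both may come from the shared arrays. The count moved to 190 with array weights, to 41 with replicates 1 and 2 of each biofilm stage averaged, to 48 without exponential replicate 3, to 54 without exponential replicate 2, and to 56 and 55 without attachment replicates 1 and 2. The mean of the 3 stages differed from the mean of the 2 phases in 3207 probe sets, 1595 higher and 1612 lower. In this contrast 42 of 50 RpoS genes were lower and 4 higher (42 and 4 adjusted over the list alone; list adjusted p = 5.84e-09, and adjusted p = 0.273 with an estimated correlation), the largest loss being that of phoH (-3.51 ± 0.13 on the log2 scale). The stationary arrays weigh heavily in it: against exponential cells alone, 12 of the 50 were higher and 22 lower at maturation (12 and 22 adjusted over the list alone; list adjusted p = 0.491, and adjusted p = 0.889 with an estimated correlation). At attachment, as given above, the RpoS genes that passed against exponential cells were all lower. The loss at that stage thus does not rest on the stationary cells. It rests on the exponential arrays, sampled at 6 h against 2 h for attachment. The design cannot separate growth mode from sampling time there. For the mean of the stages against the mean of the phases, 68.7% of the probe sets that passed were higher with the values as deposited, against 49.7%. The median of all genes then shifted by 0.39.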

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

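The tests of background, of scaling, of operon position and of other splits in this part were chosen only after the results were seen.

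Ageing differed between the biofilm and the planktonic culture. The change from attachment to colony formation and the change from exponential to stationary phase differed in 3046 probe sets. The difference, biofilm change minus planktonic change, was positive in 1511 and negative in 1535 of them. A positive difference can also mean a smaller fall in the biofilm than in the planktonic culture. With the values as deposited, 74.5% of the probe sets that passed had a positive difference, against 49.6%. The median of all genes then shifted by 1.01. In log2 units, the median difference over a list was -4.08 for fatty acid degradation, -1.80 for the RpoS regulon, -1.75 for toxin-antitoxin pairs, -1.56 for chemotaxis, -1.40 for flagella, -1.38 for uptake of alternative carbon sources, -1.28 for iron acquisition, -1.15 for colanic acid synthesis and -0.87 for iron-sulfur cluster assembly. The last of these lists did not pass with the replicate block (adjusted p = 0.0514, against 0.0431). The median was 0.91 for glycolysis, 1.31 for translation factors and RNA polymerase, 1.33 for cell division, 1.53 for copper and zinc homeostasis, 1.80 for fatty acid synthesis, 1.88 for aminoacyl-tRNA synthetases, 2.22 for acid resistance, 2.59 for ribosomal proteins, 2.72 for amino acid biosynthesis, 3.10 for aerobic respiration and 3.32 for purine and pyrimidine synthesis. These medians use fitted values, and many of the genes lay below background on the stationary arrays. Only 2 of 11 chemotaxis, 10 of 42 flagellar and 5 of 21 colanic acid genes lay above background on any of the 15 arrays. The medians of these lists therefore mostly compare signal below background. The list adjusted p lay between 4.53e-16 (ribosomal proteins) and 0.0465 (acid resistance), and with an estimated correlation between 0.0658 (aminoacyl-tRNA synthetases) and 0.645 (acid resistance), so none of these lists passed with it. Those of flagella, colanic acid synthesis, glycolysis, cell division and copper and zinc homeostasis were lost with the filter on dim probe sets. That of acid resistance was lost with the values as deposited, and that of alternative carbon sources with only genes above background.

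Most probe sets differed between the stationary arrays and the other arrays (3297 against exponential cells). The quantile normalization as the whole cause is argued against, since 2679 of these (81.3%) passed in the same direction with the values as deposited. How the deposited values were scaled is not known, so an effect of that scaling stays open. Loss of the promoter-proximal part of transcripts, which needs a positive correlation of gene position with the change, stays open: the median was -0.0952 over 20 operons with genes above background (95% bootstrap interval -0.298 to 0.165, permutation p = 0.497) and -0.197 over 34 operons with all genes (permutation p = 0.0426). Background hybridization stays open as well. Of the 1317 probe sets at least 2-fold higher, 42.5% lay above background on a stationary array, against 23.4% of all gene probe sets. They were picked for higher signal on these arrays, so the larger share follows from the selection and does not count against this cause. The other gains were set at signal below background. A true change of state in stationary cells, the biological explanation that the design gives, stays open for the genes above background.

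Of 2886 intergenic probe sets, which no comparison used, 246 were higher and 144 lower at attachment than in exponential cells, 287 and 246 at colony formation, and 660 and 473 at maturation. Of those higher, 158, 187 and 471 lay above background on an array of the stage.

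The signal of the DapX control probe sets for the 3' end over that for the 5' end was -5.67 to -5.06 on the log2 scale on the stationary arrays and 0.52 to 3.42 on the others. For ThrX the ratio moved the other way, from between -1.37 and -0.73 at attachment and colony formation to between 2.02 and 2.53 on the stationary arrays. It was -0.36 to 0.22 in exponential cells and 0.49 to 1.93 at maturation, so its rise was not limited to the stationary arrays. PheX lay between 0.09 and 1.38 on the stationary arrays, which overlapped the others (-1.25 to 1.25). LysX stayed positive and TrpnX negative on all arrays. Whether these controls were added to the samples is not given in the sources used here.

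Of the other splits of the arrays, those of 3 against 3 are too few for a share under 0.05. The real split was the 1 of 10 with the largest count each time, and the highest count of another split was 4 for maturation against colony formation (real 1898), 2 for maturation against exponential cells (real 2019) and 0 for the 8 other pairs of groups. For the biofilm against the planktonic mean, 1 of 100 splits, the real one, reached 3207 probe sets, and the highest other gave 2201. For the difference in ageing, 1 of 100 reached 3046 and the highest other gave 2861. For those shared by all 6 comparisons, 1 of 100 reached 85 and the highest other gave 1. No other split reached these 3 counts. The highest other counts for the pair of contrasts come near the real ones, so these counts say little on the grouping beyond the large differences between the arrays. The other splits put unlike arrays into 1 group, which widens the spread within groups. Low counts there, as for the pairs of groups and for all 6 comparisons, were thus largely set in advance. They do not count in favour of the grouping.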

How the results depend on the processing

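A set of 3 alternatives was chosen after seeing the data: leaving the stationary arrays out of normalization and fit, keeping only genes above background on at least 3 arrays, and averaging replicates 1 and 2 of each biofilm stage. Under the alternatives 250 counts of probe sets stayed within 1.5 times the reported count and 13 did not. Array weights raised the count to 1749 (attachment against exponential), 1964 (colony formation against exponential), 2213 (colony formation against attachment), 2848 (maturation against colony formation) and 190 (all 6 comparisons); the cause was not tested. Averaging replicates 1 and 2, which leaves 2 samples per biofilm stage, gave 437 for attachment against exponential, 505 for colony formation against attachment and 41 for all 6. Leaving out 1 array gave 504 (without attachment replicate 2) to 715 for attachment against exponential, and 48 (without exponential replicate 3) to 106 (without maturation replicate 3) for all 6, with 56 and 55 without attachment replicates 1 and 2 and 54 without exponential replicate 2. The 1.5-fold limit was not passed in any other of these counts. Without the stationary arrays 791 probe sets passed for attachment, 975 for colony formation and 2121 for maturation against exponential cells, and with only genes above background 733, 864 and 1700. The replicate block tied same-numbered arrays of all 5 groups, the planktonic ones included. With it, 826 probe sets passed for attachment against exponential, 1014 for colony formation against exponential and 1025 for colony formation against attachment. The counts were 1978 for maturation against colony formation and 90 for all 6, and no count moved by over 1.5 times. The block ended 4 list calls, among them that of iron-sulfur cluster assembly in the difference in ageing, the filter on dim probe sets 36, the limit to genes above background 33, the values as deposited 17, the compared groups alone 14 and array weights 13. Of the list results under the alternatives 3984 stayed and 408 lost their call, 212 of them with an estimated correlation, and 0 changed direction. Of the results for named genes 4014 stayed, 22 lost their call and 0 changed direction. Those lost were 7 for osmY and 3 for dps (attachment against exponential cells), 5 for fimH (colony formation against attachment) and 7 for znuC (maturation against exponential cells). Of 209 differences of named genes, 16 moved by over 1.5-fold when 1 array was left out, in most cases replicate 3 of colony formation. Signal over background limits the stationary arrays most, where 20.8% to 22.1% of gene probe sets lay above background.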

Other observations

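In this part the set of zinc-repressed genes, the test on their background and those on ribosomal protein genes were chosen only after the results were seen, while that on cold-induced genes outside the lists was written before their values were seen.

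A few lists of structures and signals known from biofilms of this species are given here for single comparisons. Of 7 curli genes, 0 passed between attachment and exponential cells and 0 between colony formation and attachment (0 and 0 adjusted over the list alone; list adjusted p = 0.715 and 0.942, and adjusted p = 0.805 and 0.957 with an estimated correlation). At maturation against colony formation 1 rose and 3 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.503, and adjusted p = 0.645 with an estimated correlation), and the regulator gene csgD was 3.84-fold lower (adjusted p = 0.000279), above background on 1 of 3 maturation arrays. Type 1 fimbriae had 5 of 9 members higher at colony formation than at attachment and 0 lower (7 and 0 adjusted over the list alone; list adjusted p = 0.0098, and adjusted p = 0.512 with an estimated correlation). The tip adhesin gene fimH was 4.32-fold higher (adjusted p = 0.0155), with 1 of 3 attachment arrays above background, but lost its call under 5 alternatives. Without replicate 3 of colony formation it was 8.94-fold higher (adjusted p = 5.67e-08). The list did not pass with the values as deposited. Of 12 genes for poly-N-acetylglucosamine and cellulose, 1 rose and 0 fell at colony formation against attachment (1 and 0 adjusted over the list alone; list adjusted p = 0.711, and adjusted p = 0.913 with an estimated correlation). Of 28 cyclic di-GMP genes, 3 rose and 3 fell at attachment against exponential cells (5 and 6 adjusted over the list alone; list adjusted p = 0.962, and adjusted p = 0.984 with an estimated correlation), with bluF 3.85-fold higher (1 of 3 exponential arrays above background) and the phosphodiesterase gene pdeL 5.49-fold lower (1 of 3 attachment arrays above background).

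The cold shock genes cspA, cspB, cspG and deaD were higher than in exponential cells at every biofilm stage. Cooling of the biofilm samples before the RNA was fixed was tested as one broad response over 7 cold-induced genes outside the lists. Their stage medians against exponential cells were -0.003, -0.22 and -0.71, with 0 higher at any stage. This argues against cooling that raised these 7 genes. The set left out lpxP, at a mean log2 signal of 3.53 in exponential cells and 7.30, 8.26 and 7.97 at the stages. At maturation aceE (-2.15), aceF (-1.73) and tig (-1.32) fell, and other changes there could have hidden a rise. The 7 genes therefore cannot exclude cooling. Faster growth on renewed medium is argued against at maturation, where the median of 54 ribosomal protein genes was -0.34 (quartiles -0.70 and -0.18), with 3 higher and 27 lower (3 and 16 with the values as deposited). It stays open at attachment and colony formation, where the medians were 0.0454 and -0.0659, with 3 higher and 0 lower at each. Cooling that raised only some cold-induced genes, such as a short one that reached the fastest, stays open at all stages, as does growth on glass itself.

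A set of zinc-repressed genes was lower than in exponential cells in every biofilm stage. All 6 measured genes repressed by the zinc sensor Zur (znuA, znuB, znuC, zinT, ykgM and pliG) were lower at every stage. They lay above background on the 3 exponential arrays, so their signal there was measured. For znuA, zinT, ykgM and pliG this was largely set by the naming rule. It asked for a mean in the higher group above the median of all genes, so these 4 are no test of signal near background. For znuC at maturation (adjusted p = 0.0276) the difference was lost under 7 alternatives, so the pattern at that stage rests on the other 5 genes. Most of these 6 genes drew attention to the pattern, so their number is no test of a more repressed Zur regulon. zur (b4046), the gene of the sensor, chosen after its values were seen, was higher in the biofilm in all 6 comparisons. Its mean log2 signal was 8.49, 8.81 and 8.59 at the stages and 7.97 in exponential cells. Whether this bears on the 6 genes was not tested. Zinc supply in the flow cells may have differed from that in the planktonic cultures, which the design cannot separate from the growth mode and which was not tested.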
